A study of Mus musculus with 6 samples.

How the data were processed

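Gene expression was measured by RNA sequencing in 6 libraries of RAW264.7, a mouse monocyte/macrophage cell line that can be driven towards osteoclasts, the bone-resorbing cells, by the cytokine RANKL. Per the labels, all 6 samples belonged to an osteoclast differentiation protocol in which cells 3 days past confluence received RANKL at 50 ng/mL. The labels put 3 samples under RANKL and 3 under albiflorin, a monoterpene glycoside of peony root; no untreated sample was analysed here, and the dose and time of albiflorin are not given in the sources used here. The protocol text of every sample names RANKL, but whether the cells labelled albiflorin received both is not stated apart from that.

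Samples were grouped by their titles, and columns of the tables were matched to samples by group letter and replicate number. The deposited table of raw counts holds whole-number reads per gene for each of the 6 libraries, and a matching deposited table holds FPKM values made by the authors. Per the submitters' processing notes, the tools named were CASAVA 1.8, fastp, HISAT2 2.2.1, featureCounts 2.0.6-p3 and DESeq2 1.42.0, with no role or order. The genome build is not given in the sources used here; the gene identifiers in the deposited count table carry the prefix that Ensembl uses for the C57BL/6NJ strain assembly, and all coordinates printed are those of that table. RAW264.7 is of BALB/c origin, so reads over strain variants can be counted less well. The authors' FPKM values equalled the deposited counts divided by the listed gene length and by 1 total per library, which differed from the column total by -0.95% to 1.65%. Whether counting used strand is not given in the sources used here, so overlapping and antisense genes could share reads.

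The count table held 41921 rows, of which 11512 had no gene symbol and 825 were additional genes without a biotype that took 1.95% to 2.15% of the counts. Rows without a symbol kept their identifier, except 299 that were named from the single mouse protein match in the deposited description. Another 24 names had been turned into dates and were not named here. No row lay on the mitochondrial or the Y chromosome. Genes that share reads with processed pseudogenes, such as the ribosomal protein genes, are uncertain.

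Genes higher or lower with albiflorin were tested with edgeR 4.0.16 (R 4.3.3) on the deposited counts: filterByExpr, TMM scaling, the quasi-likelihood F-test on group alone, and Benjamini-Hochberg adjusted p under 0.05. Log2 fold changes are albiflorin over RANKL, and each SE is the absolute log2 fold change divided by the square root of its F statistic. CPM values (normalised read counts) use the TMM-scaled library sizes and are given as mean ± SD with n = 3 per group. The 43 gene lists were fixed before the data were examined; 928 of their 996 different symbols were matched to rows. Lists with at least 5 tested genes were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, and again with a correlation estimated from the residuals. The latter setting takes its degrees of freedom from the 6 libraries and not from the genes, so a list can hardly pass in it. Its failures therefore do not tell which calls under the preset correlation are wrong.

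Genes were named by a rule that was also fixed in advance. It took 10 genes whatever their result, among them Rap1a, Mapk3, Pink1, Acp5, Ctsk, Nfatc1, Dcstamp and Mmp9. Some genes that the rule took are not reported here. It added the 10 largest increases and the 10 largest decreases among called genes with at least 5 CPM in 1 group, no overlap between the groups' libraries and a proper symbol, and up to 4 called genes with the smallest p in each list that passed its test or held at least 3 called genes. Any other gene named was chosen after its values were seen.

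The alternatives fixed in advance were RLE scaling, DESeq2 1.42.0, limma-voom, no filter and a stricter filter on low counts, the replicate number as a block, leaving out each library, limma on log2(FPKM + 1) and log2(FPKM + 0.1), a fold threshold, a test against a 1.2-fold change, and for lists the estimated correlation and fry. After a trend with gene length had been seen in the data, 3 further alternatives were added. The first removed from each library its lowess trend (span 0.3, fitted on genes with a mean log2 CPM over 3) on the gene length in the deposited table, and another removed a GC trend as well. The last, added after the results of those 2 had been seen, used the mRNA length of the principal transcripts in GENCODE M21, matched by symbol, because the listed gene length joins all exons of a gene. An mRNA length was found for 81.05% of the tested genes, 96.1% of the tested protein-coding genes and 88.4% of the called genes. Genes without one took the trend on the listed gene length. Beside results in the report, "trend removed" refers to this mRNA-length version. The closing section gives the gene counts under all 3, and where a call that ended with this version was kept under another, that is said beside the result. No coordinates were taken from GENCODE M21.

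Library totals ran from 13673284 to 15489482 counts, at which 3 counts correspond to 0.191 to 0.223 CPM (floors that cover counting error only). On simulated counts for this comparison with 200 genes changed among 13005 tested, the test recovered 84.8% of 1.41-fold changes, and 100% of 2-fold and of 4-fold changes, with 12 false calls among 202. The changed genes were drawn from those with a mean over 5 CPM, so this recovery does not cover lower genes. Every simulated gene had the spread typical of its expression level, so genes more variable than that are not covered either. With the measured gene-length trend added to the simulation (13015 genes), 1235 of 1426 calls were false without a correction and 15 of 208 with the gene-length correction. Calls were false there by definition where only the added trend changed a gene. The correction fitted the same kind of trend on the same lengths, so its recovery was largely fixed in advance. The simulation therefore does not tell which calls in the real libraries are false. The GC and mRNA-length corrections were not tested on simulated counts. Every pair of libraries differed by more than sampling noise, with chi-square per degree of freedom of 3.59 to 8.62 within groups, so no library was counted as a copy of another.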

Results

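RNA sequencing counts were available for 6 RAW264.7 libraries labelled as osteoclast differentiation, 3 labelled RANKL and 3 labelled albiflorin. The RANKL libraries held 13673284, 15489482 and 14663862 counts, and the albiflorin libraries 15200418, 13708041 and 14311565. The comparison asked how expression differed between cells labelled albiflorin and cells labelled RANKL. The protocol text names RANKL for all 6 samples, without saying that albiflorin was added to it. The series title names osteoclast mitophagy and Rap1a/ERK signalling as its subject. Nothing in the labels says that replicates came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

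Immediate-early genes, which are transcribed within minutes of a stimulus, made up 8 of the 10 largest increases with albiflorin under the naming rule. Fos, an AP-1 transcription factor subunit (MGP_C57BL6NJ_G0020349, chromosome 12, 88741461 to 88744847), rose from 19.8 ± 4.5 to 258 ± 99.5 CPM (SD, n = 3 per group), a log2 fold change of 3.70 ± 0.217 (SE; edgeR quasi-likelihood test, adjusted p = 1.06e-07). Its relative Fosb (chromosome 7, 18160456 to 18167782) rose from 0.513 ± 0.171 to 18.7 ± 27.0 CPM (log2 fold change 5.14 ± 1.09, adjusted p = 0.00346). The MAP kinase phosphatase gene Dusp1 rose by 2.45 ± 0.309, Zfp36, which encodes an mRNA-destabilising protein, by 1.65 ± 0.142, and Ier2 by 1.22 ± 0.0889 on the log2 scale. Egr1 (1.15 ± 0.257), Jun (1.12 ± 0.126), Junb (0.94 ± 0.0761), Klf2 (0.97 ± 0.133) and Ier3 (0.84 ± 0.111) also rose. Of 18 tested genes of this list 10 rose and 0 fell, with the same count adjusted over the list alone, and the median log2 fold change was 0.89. The list passed the list test (adjusted p = 2.97e-05) but not with an estimated correlation (adjusted p = 0.432 with an estimated correlation). Atf3 (0.06 ± 0.114, adjusted p = 0.77), Nr4a1 (0.14 ± 0.211, adjusted p = 0.688) and Btg2 (-0.04 ± 0.0725, adjusted p = 0.743) did not pass. Without albiflorin replicate 3 the log2 fold change of Fosb was 2.61 and that of Egr1 0.57, both still called. Fosb did not pass with limma-voom (adjusted p = 0.115), nor did Egr1 with DESeq2 (adjusted p = 0.0579) or on log2(FPKM + 1) (adjusted p = 0.094).

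**Figure D1:**
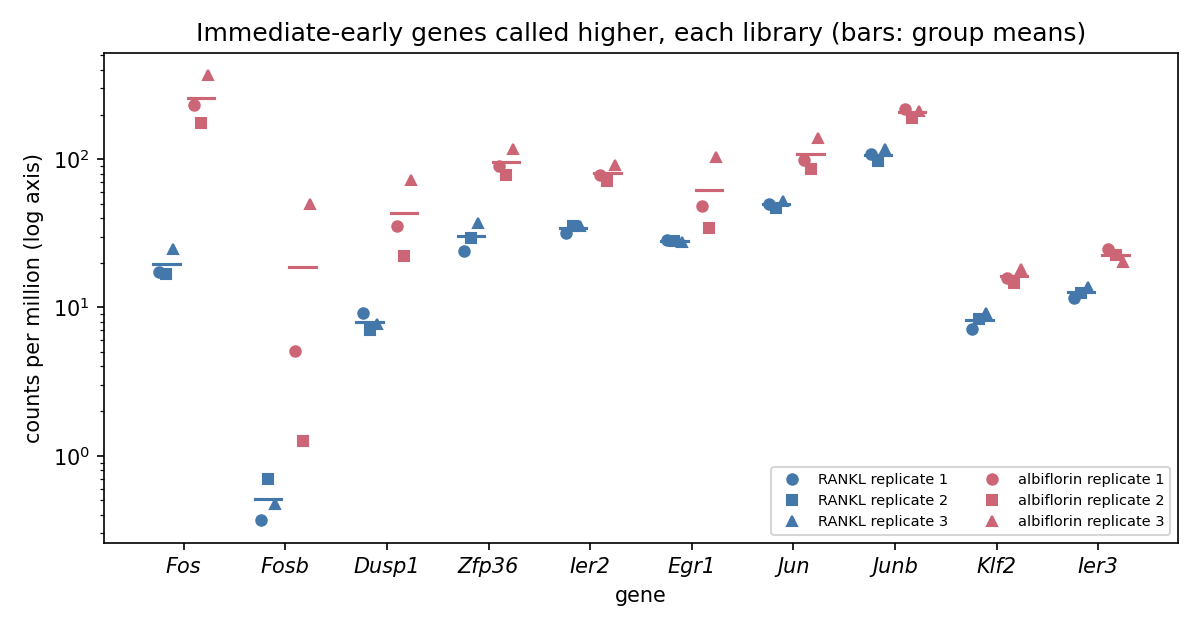
CPM (log axis) of the 10 immediate-early genes called higher, in each of the 3 RANKL and 3 albiflorin libraries; points are libraries and bars are group means. All 3 albiflorin libraries lie above all 3 RANKL libraries for each gene, and for Fos the group means are 19.8 and 258 CPM.

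In all, 1631 genes were higher and 1496 lower with albiflorin among 13158 tested, and most changes were small. Called genes were 23.8% of those tested, so a list can hold called genes without any change of its own. The median absolute log2 fold change of called genes was 0.33, and 39 higher and 41 lower genes changed by 2-fold or more. That balance shifted to 14 higher and 83 lower with the mRNA-length trend described next removed, and to 15 and 95 with the gene-length trend removed. How many of these genes were not protein-coding or had no mRNA length was not counted. The groups' libraries did not overlap for 40.1% of tested genes, where chance gives 10% for each gene. All genes share the same libraries, so a shift common to many genes raises this share, and the excess is no test against chance. The direction followed transcript length. Among 10619 protein-coding genes the median log2 fold change was 0.37 for mRNAs under 1000 nt, of which 58.5% were called higher, and -0.29 for those over 8000 nt, of which 59.9% were called lower. Across genes, which are not independent replicates, the rank correlation of log2 fold change with mRNA length was -0.623, and it was -0.619 without ribosomal protein and respiratory-chain genes. With this trend removed, an alternative chosen after seeing the data, 617 genes were higher and 719 lower, of which 399 and 485 were also called before. Protein-coding genes with an mRNA length then held more higher than lower calls in every length class except under 1000 nt (21 and 40). The excess of lower calls thus lay among the other genes, and the removal itself may have added to it. Leaving out RANKL replicate 2 gave 1010 higher and 914 lower, leaving out albiflorin replicate 1 gave 984 and 977, and leaving out albiflorin replicate 2 gave 1025 and 999.

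**Figure D2:**
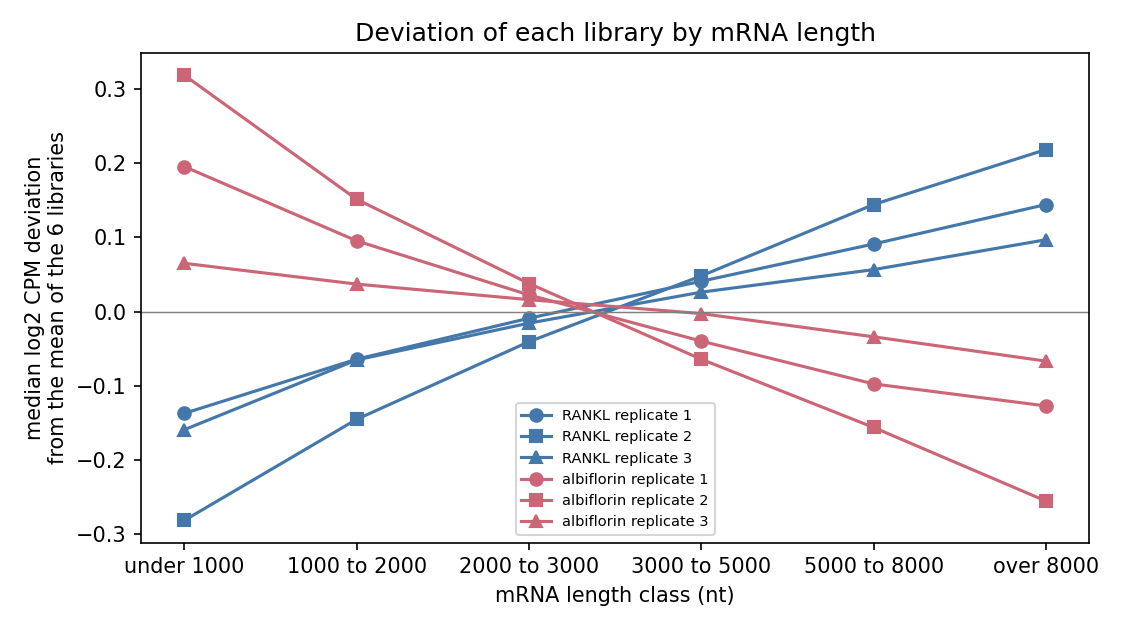
Median deviation of log2 CPM from the mean of the 6 libraries (vertical axis) for protein-coding genes with a mean log2 CPM over 3, in 6 classes of mRNA length in nt (horizontal axis), 1 line per library. Under 1000 nt the albiflorin libraries sit at 0.0649 to 0.318 and the RANKL libraries at -0.281 to -0.137, and over 8000 nt the albiflorin libraries sit at -0.255 to -0.0667 and the RANKL libraries at 0.0966 to 0.218.

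The other genes among the 10 largest increases were Rgs1, a regulator of G-protein signalling (log2 fold change 1.12 ± 0.161), and Etfb, a mitochondrial electron-transfer flavoprotein subunit (1.07 ± 0.202). The 10 largest decreases were Hipk2, Ndst1, Dnah17, Crybg3, Adnp, Tet3, Snx29, Kcnq1ot1, Farp2 and Srcap. The kinase gene Hipk2 fell from 53.2 ± 10.3 to 24.8 ± 7.43 CPM (log2 fold change -1.09 ± 0.168, edgeR adjusted p = 0.000535). Ndst1, a heparan sulphate-modifying enzyme, stood at -1.03 ± 0.173 and the 5-methylcytosine oxidase gene Tet3 at -0.86 ± 0.119. With the length trend removed, Hipk2 (-0.86), Ndst1 (-0.84) and Tet3 (-0.68) were still called, and Dnah17 (adjusted p = 0.13), Kcnq1ot1 (adjusted p = 0.0738) and Srcap (adjusted p = 0.174) were not. Dnah17 kept its call with the gene-length trend removed (0.0386) and with gene length and GC removed (0.046), and Kcnq1ot1 with gene length and GC removed (0.0319). Srcap was also not called without RANKL replicate 1 (adjusted p = 0.0656), RANKL replicate 2 (0.0595) or albiflorin replicate 2 (0.0619). On log2(FPKM + 1) neither Adnp (0.0783) nor Farp2 (0.0683) was.

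Of the genes behind the series title, Rap1a and Mapk3 were not called. Rap1a, a small GTPase (MGP_C57BL6NJ_G0028136, chromosome 3, 111103566 to 111188766), stood at 267.8 ± 9.23 CPM with RANKL and 265.0 ± 10.1 CPM with albiflorin (log2 fold change -0.01 ± 0.0598, edgeR adjusted p = 0.891). It was called lower with the gene-length and GC trends removed (-0.21, adjusted p = 0.0198) but not with the mRNA-length trend removed (-0.07, adjusted p = 0.433). Both are alternatives chosen after seeing the data. Mapk3, which encodes ERK1, had a log2 fold change of 0.15 ± 0.0593 (adjusted p = 0.0798). RNA levels do not measure the activity of these proteins. Genes of the Rap1 GTPase cycle were lower as a list: 0 of 23 rose and 10 fell, also when adjusted over the list alone (adjusted p = 0.000844; adjusted p = 0.514 with an estimated correlation). The exchange factor genes Rapgef5 (-0.43 ± 0.0759) and Rapgef1 (-0.31 ± 0.06), the GTPase-activating Sipa1l3 (-0.48 ± 0.0961) and talin 1 (Tln1, -0.34 ± 0.0651) fell. The list pools exchange factors, GTPase-activating genes that oppose them and adhesion genes such as Tln1, so its fall gives no direction of Rap1 activity. With the length trend removed the list no longer passed (adjusted p = 0.105) and its count was 0 higher and 1 lower, Rapgef5. Rapgef1 (adjusted p = 0.216), Sipa1l3 (0.0636) and Tln1 (0.27) were then not called. The list did pass with the gene-length trend removed (adjusted p = 0.0227, 1 higher and 5 lower; adjusted p = 0.477 with an estimated correlation) and with gene length and GC removed (0.0123). Rapgef1 kept its call under both (0.0266 and 0.0474), and Tln1 with the gene-length trend removed (0.0281). On log2(FPKM + 1) Sipa1l3 was not called either (0.0546). Rap1, ERK and mitophagy are named in the series title, and whether these samples led to those themes is not given in the sources used here, so these lists are not treated as independent evidence of direction.

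ERK pathway components did not pass as a list (3 of 26 higher, 7 lower; 4 and 8 adjusted over the list alone; adjusted p = 0.404). Ptpn11, a phosphatase that relays receptor signals to Ras, fell by 0.38 on the log2 scale (SE 0.0679). Genes transcribed in response to ERK were higher as a list, with 5 of 21 higher and 1 lower (6 and 1 adjusted over the list alone, adjusted p = 0.0458; adjusted p = 0.606 with an estimated correlation). Its called members were Fos, Ier2, Egr1, Ier3 and Dusp6, an ERK phosphatase gene (0.63 ± 0.0748), and Egr3, which was lower (not called with the trend removed, adjusted p = 0.109, but called with the gene-length trend removed, 0.017). Fos, Ier2, Egr1 and Ier3 are also members of the immediate-early list. Other members were not called, among them Spred1 (-0.05, adjusted p = 0.61), Dusp4 (-0.20, adjusted p = 0.115) and Ccnd1 (-0.07, adjusted p = 0.448). The list call ended without RANKL replicate 1 (adjusted p = 0.0839), RANKL replicate 3 (0.0816) or albiflorin replicate 1 (0.245), with the stricter filter (0.141) and on log2(FPKM + 1) (0.262). It held with the trend removed (0.00115), with the gene-length trend removed (0.0227) and with gene length and GC removed (0.0129). With an estimated correlation as well, the first 2 of these did not pass (adjusted p = 0.418 and 0.56 with an estimated correlation).

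Mitophagy genes did not move together: 8 of 40 rose and 2 fell, also when adjusted over the list alone, and the list did not pass (adjusted p = 0.252). Pink1, the kinase that marks damaged mitochondria, stood at 32.2 ± 2.21 CPM with RANKL and 33.4 ± 2.44 CPM with albiflorin (log2 fold change 0.05 ± 0.0882, edgeR adjusted p = 0.732). The import subunit gene Tomm7 (0.71 ± 0.0792) and the mitophagy receptor gene Bnip3 (0.45 ± 0.0725) rose, and the mitochondrial fusion gene Mfn2 (-0.33 ± 0.0678) fell; these 3 calls held with the length trend removed. Gabarap (0.33 ± 0.0611) rose, but not with the trend removed (adjusted p = 0.19), and again with gene length and GC removed (0.0387). Core autophagy genes (6 higher, 8 lower of 35; 7 and 9 adjusted over the list alone; adjusted p = 0.446), mitochondrial dynamics (2 and 2 of 19, also adjusted over the list alone, adjusted p = 0.887) and mitochondrial biogenesis (3 and 3 of 16, also adjusted over the list alone, adjusted p = 0.855) did not pass.

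Of 15 tested resorption genes 3 rose and 3 fell (4 and 3 adjusted over the list alone; adjusted p = 0.354). Acp5, which encodes the osteoclast acid phosphatase TRAP, stood at 22.9 ± 2.11 and 28 ± 1.59 CPM (log2 fold change 0.29 ± 0.0952, edgeR adjusted p = 0.0371). That call ended with the trend removed (0.07, adjusted p = 0.66), with DESeq2 (0.0664) and without RANKL replicate 1 (0.142), RANKL replicate 2 (0.0975), albiflorin replicate 1 (0.099) or albiflorin replicate 2 (0.13). Nfatc1, the transcription factor that drives osteoclast differentiation, fell from 142.7 ± 7.45 to 122.3 ± 5.5 CPM (-0.22 ± 0.0633, edgeR adjusted p = 0.018). Its call ended with the trend removed (-0.11, adjusted p = 0.19) and without RANKL replicate 2 (0.0816), albiflorin replicate 1 (0.0506) or albiflorin replicate 2 (0.0575). The fusion receptor gene Dcstamp (0.05, adjusted p = 0.745) and Mmp9 (0.47, adjusted p = 0.0579) were not called, though Mmp9 passed without RANKL replicate 3 (0.0406) or albiflorin replicate 3 (0.0159) and with no filter on low counts (0.0156). Ctsk, which encodes the bone matrix protease cathepsin K, was too low to test, at 0.457 ± 0.121 and 0.693 ± 0.2 CPM, and the calcitonin receptor gene Calcr had 0 counts in all 6 libraries, which allows up to 0.223 CPM in albiflorin replicate 2, where the floor was highest. Plekhm1 (-0.41 ± 0.0659) fell and the carbonic anhydrase gene Car2 (0.29 ± 0.0672) rose, though Car2 was not called with the trend removed (adjusted p = 0.0932), against 0.0485 with the gene-length trend removed and 0.0373 with gene length and GC removed. Osteoclast transcription factors held 7 higher and 2 lower of 21 (8 and 2 adjusted over the list alone, adjusted p = 0.123). The members with the smallest p were Fos, Junb, Jun and Jund, of which Fos, Junb and Jun are also members of the immediate-early list. The median log2 fold change of the list was 0.00985 (0.0249 with the trend removed) and its mean 0.37. The rise was thus not shared by the list as a whole. The list passed as higher with the trend removed (adjusted p = 0.0242), with the gene-length trend removed (0.00314), with gene length and GC removed (0.000748), with fry (0.0381) and without albiflorin replicate 2 (0.0236). With an estimated correlation it did not (adjusted p = 0.606 with an estimated correlation, 0.476 with the trend removed as well, and 0.427 with the gene-length trend removed as well). Fusion genes held 1 higher and 1 lower of 10 (1 and 0 adjusted over the list alone, adjusted p = 0.894). Receptors and signalling held 2 and 4 of 15 (2 and 6 adjusted over the list alone, adjusted p = 0.0782) and passed as lower without albiflorin replicate 3 (0.0243), against adjusted p = 0.606 with an estimated correlation over all 6 libraries. Inhibitors of osteoclast formation held 5 and 1 of 17 (5 and 2 adjusted over the list alone, adjusted p = 0.331).

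Podosome and actin ring genes, the adhesion apparatus of osteoclasts, were lower as a list, with 2 of 23 higher and 7 lower (3 and 10 adjusted over the list alone, adjusted p = 0.0359; adjusted p = 0.514 with an estimated correlation). The ubiquitin ligase gene Cbl (-0.50 ± 0.076) and vinculin (Vcl, -0.48 ± 0.0822) fell, and the Arp2/3 subunit gene Arpc3 (0.42 ± 0.0675) rose. Tln1, which also fell, and Fermt3 are members of both this list and the Rap1 list, so these lists are not independent. Without RANKL replicate 1 (adjusted p = 0.0605), RANKL replicate 3 (0.0639) or albiflorin replicate 1 (0.0677), or with the trend removed (0.115), the list did not pass, nor with the gene-length trend removed (0.105) or gene length and GC removed (0.169). Cbl and Vcl were still called with the trend removed, and Arpc3 was not (adjusted p = 0.278), though it was with the gene-length trend removed (0.00147).

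Inflammatory genes were higher with albiflorin. Of 16 inflammatory mediators 9 rose and 0 fell (10 and 0 adjusted over the list alone, adjusted p = 0.000481; adjusted p = 0.333 with an estimated correlation), among them the chemokine gene Ccl3 (0.68 ± 0.0684) and Tnf, which rose from 44.1 ± 7.81 to 70.9 ± 8.09 CPM (0.68 ± 0.107, edgeR adjusted p = 0.000589). Among NF-kB targets 8 of 18 rose and 0 fell, also adjusted over the list alone (adjusted p = 0.00302; adjusted p = 0.432 with an estimated correlation), including the inhibitor gene Nfkbia (0.50 ± 0.0659) and Relb (0.40 ± 0.0864). Tnf is a called member of both the NF-kB target and inflammatory mediator lists, so these lists are not independent. Antigen presentation genes held 8 higher and 0 lower of 19, also adjusted over the list alone (adjusted p = 0.00891; adjusted p = 0.514 with an estimated correlation), with Cd74 (0.42 ± 0.061) and H2-K1 (0.49 ± 0.0936), a member of a gene family whose copies share reads. With the trend removed, 5 inflammatory mediators were higher (median 0.22), 7 NF-kB targets (median 0.18) and 5 antigen presentation genes (median 0.12). These 3 lists then passed (adjusted p = 0.00115, 0.000231 and 0.0193, in that order), but not with an estimated correlation as well (adjusted p = 0.222, 0.336 and 0.418 with an estimated correlation). Antigen presentation did not pass with the gene-length trend removed (0.105) or with gene length and GC removed (0.0537). Interferon-stimulated genes (3 and 3 of 30, also adjusted over the list alone, adjusted p = 0.57) and macrophage identity genes (3 and 3 of 18, 3 and 4 adjusted over the list alone; adjusted p = 0.706) did not pass.

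**Figure D3:**
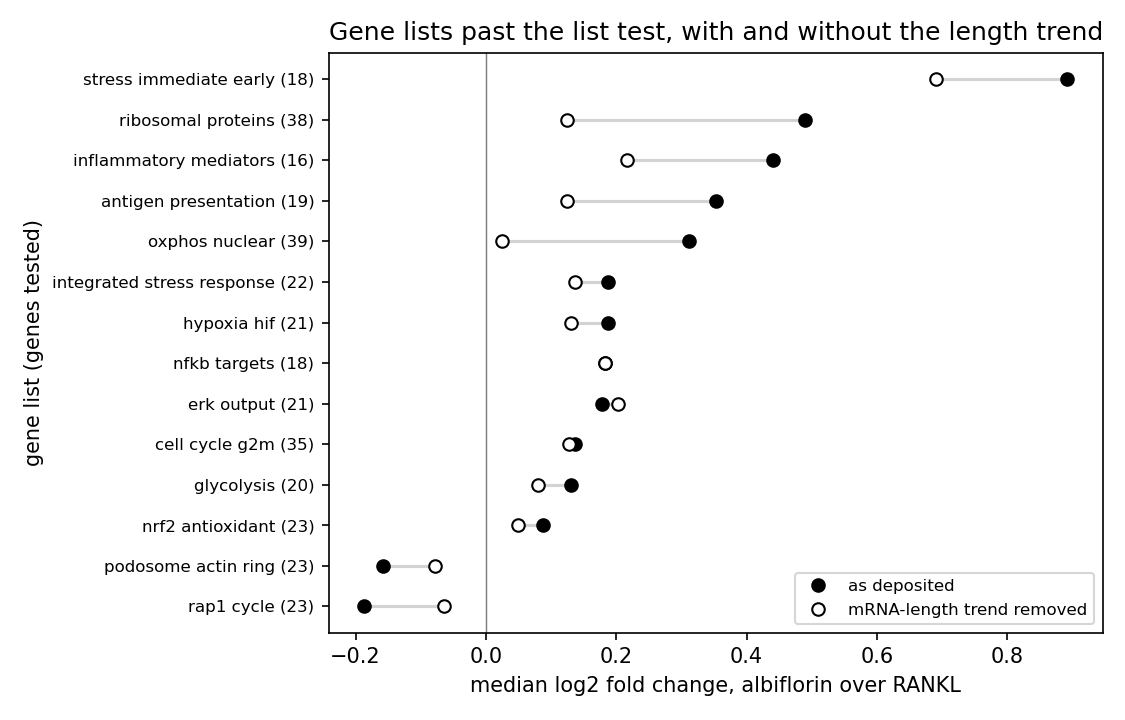
Median log2 fold change (horizontal axis, albiflorin over RANKL) of the 14 gene lists past the list test, with the number of tested genes in brackets; filled points are the deposited counts and open points have the mRNA-length trend removed. The median of nuclear-encoded respiratory-chain genes moved from 0.31 to 0.02 and that of immediate-early genes from 0.89 to 0.69.

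Genes with short mRNAs for translation and respiration were higher. Cytosolic ribosomal protein genes held 34 higher and 0 lower of 38, also adjusted over the list alone (median 0.49, adjusted p = 7.49e-16; adjusted p = 0.432 with an estimated correlation), and all protein-coding genes with a ribosomal protein symbol took 4.60 ± 0.116% of the counts with RANKL and 6.20 ± 0.533% with albiflorin (exact two-sided permutation p = 0.1, the lowest that 3 against 3 can give). Rpl13 rose by 0.65 ± 0.0799 and Rps20 by 0.65 ± 0.0842. With the trend removed 12 rose, the median was 0.12 and the list still passed (adjusted p = 1.88e-06; adjusted p = 0.38 with an estimated correlation). Nuclear-encoded respiratory-chain genes held 28 higher and 0 lower of 39 (31 and 0 adjusted over the list alone, adjusted p = 6.36e-10; adjusted p = 0.514 with an estimated correlation), with Cox7a2 at 0.72 ± 0.078 and Sdhc at 0.37 ± 0.0599. With the trend removed 4 rose, 1 fell and the list did not pass (adjusted p = 0.115). It passed with the gene-length trend removed (adjusted p = 6.01e-05, 9 higher and 0 lower; adjusted p = 0.443 with an estimated correlation) and with gene length and GC removed (adjusted p = 3.68e-05).

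The integrated stress response, hypoxia, Nrf2, glycolysis and mitotic lists were also higher. In the integrated stress response 10 of 22 rose and 1 fell, also adjusted over the list alone (adjusted p = 0.000481; adjusted p = 0.333 with an estimated correlation), with Ppp1r15a, a phosphatase subunit gene (0.81 ± 0.106), and Atf4 (0.34 ± 0.0564). Hypoxia genes held 9 higher and 0 lower of 21, also adjusted over the list alone (adjusted p = 0.000917; adjusted p = 0.432 with an estimated correlation), with Ankrd37 (0.74 ± 0.111) and Hilpda (0.78 ± 0.124). Nrf2 antioxidant genes held 10 higher and 0 lower of 23, also adjusted over the list alone (adjusted p = 0.0052; adjusted p = 0.432 with an estimated correlation), led by the ferritin light chain gene Ftl1 (0.74 ± 0.0832). Glycolysis held 5 higher and 0 lower of 20, also adjusted over the list alone (adjusted p = 0.042; adjusted p = 0.606 with an estimated correlation), with Aldoa (0.47 ± 0.0613) and the glucose transporter gene Slc2a1 (0.29 ± 0.0595). The glycolysis call ended without RANKL replicate 2 (0.138), RANKL replicate 3 (0.0764) or albiflorin replicate 3 (0.216), and with the stricter filter (0.057). It also ended with the replicate block (0.0846), on log2(FPKM + 1) (0.0504) and with fry (0.0638). Aldoa was not called with the trend removed (0.401), but was with the gene-length trend removed (0.000257). Mitotic (G2/M) genes held 14 higher and 1 lower of 35 (15 and 1 adjusted over the list alone, adjusted p = 0.00302; adjusted p = 0.333 with an estimated correlation), with Cdk1 at 0.35 ± 0.068. With the trend removed the numbers higher were 6 for the integrated stress response, 5 for hypoxia, 3 for Nrf2, 2 for glycolysis and 7 for mitotic genes. These 5 lists then passed, in that order with adjusted p = 0.000301, 2.22e-05, 0.00502, 0.00446 and 4.4e-07. None did with an estimated correlation as well (adjusted p = 0.236, 0.222, 0.222, 0.442 and 0.222 with an estimated correlation).

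Lists without a call were the S-phase genes (6 and 3 of 35, adjusted p = 0.745), p53 targets (4 and 1 of 22, adjusted p = 0.133), apoptosis (5 and 0 of 24, adjusted p = 0.252), the unfolded protein response (6 and 4 of 23, adjusted p = 0.258) and ribosome biogenesis (6 and 3 of 28, adjusted p = 0.603). The same held for lysosome genes (4 and 6 of 34, adjusted p = 0.887), the V-ATPase (5 and 2 of 18, adjusted p = 0.293), iron handling (5 and 1 of 17, adjusted p = 0.252), cholesterol synthesis (0 and 3 of 23, adjusted p = 0.887) and fatty acid and lipid genes (3 and 6 of 27, adjusted p = 0.258). In each bracket the first count is genes higher and the next genes lower. Adjusted over the list alone the counts were 4 and 0 for apoptosis, 7 and 4 for the unfolded protein response, 9 and 5 for ribosome biogenesis and 5 and 7 for lysosome genes, and for the other lists of this paragraph they did not change. The lysosome list had a median log2 fold change of 0.0255 and a mean of -0.000188. With fry, which does not compare a list with other genes, p53 targets (0.0479), apoptosis (0.0416) and iron handling (0.0381) passed as higher, against adjusted p = 0.514, 0.604 and 0.514 with an estimated correlation. Within these lists the lipid synthesis genes Acaca (-0.57 ± 0.0849) and Fasn (-0.51 ± 0.078) and the lysosomal sulphatase gene Arsb (-0.52 ± 0.0796) fell, also with the trend removed.

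Summed levels of other cells' markers differed between the lists. Fibroblast and osteoblast markers summed to 6.69 ± 1.06 CPM with RANKL and 5.76 ± 0.602 CPM with albiflorin, lymphoid markers to 5.65 ± 1.17 and 5.14 ± 0.801 CPM, granulocyte and mast cell markers to 2.58 ± 0.577 and 3.70 ± 0.29 CPM, and epithelial and endothelial markers to 6.20 ± 0.305 and 4.81 ± 0.0476 CPM. Dendritic cell markers summed to 274.6 ± 11.5 and 250.6 ± 4.32 CPM, of which Tcf4 made up 260.9 ± 12.8 and 236.3 ± 3.88 CPM, with 0 of 5 tested genes called, also adjusted over the list alone (adjusted p = 0.553). Replication histone genes (3 tested) were too few for the list test, and of the mitochondrially encoded genes 0 were tested.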

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

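The replicate block, the library left out and the count thresholds were among the settings fixed before the data were examined; the 3 trend removals were chosen after seeing the data. RLE scaling kept the side of the threshold and direction of all 149 tested genes of the naming rule that are covered here and 37 lists, and moved the median log2 fold change from 0.0056 to -0.000365. Replicate numbers did not pair the libraries (correlations of same-numbered deviations 0.022, -0.043 and -0.066, and not every library correlated best with its own number); with the replicate block 1358 genes were higher and 1214 lower, with 11 lists higher and 2 lower, the glycolysis list not passing (adjusted p = 0.0846). Against 1631 higher and 1496 lower, limma on log2(FPKM + 1) gave 1185 higher and 881 lower with the filter, on log2(FPKM + 0.1) 1153 and 856, and on log2(FPKM + 1) without it 20 and 9. A log2 fold change of at least 1 left 39 and 41, and the test against 1.2-fold 193 and 105; both are stricter by construction. Removing the gene-length trend gave 945 higher and 1048 lower, gene length with GC 945 and 1088, and mRNA length 617 and 719. Leaving out 1 library gave 984 to 1753 higher and 914 to 1644 lower, with fewer samples in each fit.

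Lists higher numbered 0 and lists lower 0 with an estimated correlation, against 12 and 2. The inflammatory mediator and mitotic lists had estimated correlations of -0.00304 and 0.00198, under the preset 0.01, and both had adjusted p = 0.333 in that camera setting. These values argue against correlation between genes as the reason that these 2 lists lost their call there. The degrees of freedom in that setting come from the 6 libraries, which by itself makes a call hard to reach for any list. Losing a call there thus does not decide whether a list changed. Leaving out 1 library gave 10 to 13 lists higher and 1 to 3 lower. Lists lower numbered 1, 1 and 0 with the gene-length, gene-length and GC, and mRNA-length trends removed. The Rap1 list had adjusted p = 0.514 with an estimated correlation and 0.105 with the mRNA-length trend removed, but 0.0227 with the gene-length trend removed and 0.0123 with gene length and GC removed, within a range of 0.000529 to 0.514. The ERK response list had adjusted p = 0.141 with the stricter filter, 0.262 on log2(FPKM + 1), 0.606 with an estimated correlation and 0.0123 to 0.245 without 1 library, within a range of 0.00115 to 0.606. The cause was not tested for these or for the FPKM counts.

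Among all tested genes, 3 were called in opposite directions before and after the gene-length removal and 4 before and after the mRNA-length removal. Some of the 149 genes and 37 lists changed sign, none of them called under the alternative. Removing the gene-length trend gave log2 fold changes of -0.0755 for Pink1, -0.108 for Dcstamp, -0.0093 for Tyrobp and -0.0393 for Fcer1g. Gene length with GC gave -0.0368 for Pink1, -0.111 for Dcstamp, -0.0252 for Fcer1g and -0.0279 for B2m, and mRNA length -0.00813 for Pink1, -0.0547 for Dcstamp, -0.0633 for Tyrobp, -0.115 for Fcer1g and -0.0368 for Fis1. Without 1 library Rap1a ranged from -0.0565 to 0.0127, Pink1 from -0.00421 to 0.0995 and Dcstamp from -0.00215 to 0.0759. Without 1 library the adjusted p of lists that changed direction ranged from 0.483 to 0.978 (osteoclast fusion), 0.748 to 0.974 (mitochondrial dynamics), 0.41 to 0.996 (interferon), 0.477 to 0.965 (S phase), 0.516 to 0.973 (cholesterol synthesis) and 0.662 to 0.927 (lysosome). Lists that changed direction, with adjusted p after the gene-length, gene-length and GC, and mRNA-length removals in that order, were core autophagy (0.978, 0.876, 0.811), macrophage identity (0.978, 0.828, 0.998), lysosome (0.604, 0.748, 0.998) and dendritic cell markers (0.643, 0.731, 0.811). With the mRNA-length removal alone, so did mitochondrial biogenesis (0.911), cholesterol synthesis (0.998) and the V-ATPase (0.998), and on log2(FPKM + 1) osteoclast fusion (0.99). With the mRNA-length trend removed, 63 of these 149 genes lost their call in the same direction and 5 changed sign, of which Tyrobp, Fcer1g and Fis1 had been called and lost their call too.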

Other observations

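The tests of the length pattern and of the immediate-early genes were chosen after the results were seen; the counts over other splits of the libraries were planned before. Several genes used as markers of mature osteoclasts were low in both groups. Ctsk had 0.457 ± 0.121 CPM with RANKL and 0.693 ± 0.2 CPM with albiflorin (n = 3 each), Oscar 0.113 ± 0.1 and 0.12 ± 0.108 CPM, Ocstamp 0.568 ± 0.259 and 0.691 ± 0.354 CPM, Itgb3 2.66 ± 1.26 and 1.57 ± 0.427 CPM, and Atp6v0d2 6.03 ± 0.59 and 7.79 ± 1.31 CPM. The macrophage receptor gene Csf1r stood at 1944 ± 47.9 and 1730 ± 81.5 CPM, and the RANKL receptor gene Tnfrsf11a at 87.1 ± 5.17 and 80.6 ± 7.95 CPM. Without an untreated sample, no change with RANKL could be measured. These genes were chosen after their values were seen, apart from Ctsk.

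The shift towards short mRNAs varied in size within groups: the difference between the medians of mRNAs under 1000 nt and over 8000 nt (mean log2 CPM over 3) was -0.281, -0.499 and -0.256 in the RANKL libraries and 0.322, 0.573 and 0.132 in the albiflorin libraries, on the log2 scale (exact two-sided permutation p = 0.1, the smallest 3 against 3 can give). GC content is argued against, since the rank correlation with mRNA length at a given GC content was -0.633, and so is genomic span, since the correlation with span at a given mRNA length was -0.117 against -0.514 for mRNA length at a given span. The widest range within a group was 0.642 of the difference between groups, so a difference in RNA integrity or library preparation and an effect of albiflorin on transcripts by length cannot be told apart. Small changes of genes with short or long mRNAs may therefore reflect either. For the respiratory-chain and Rap1 lists the removals differed, since both calls ended with the mRNA-length trend removed (adjusted p = 0.115 and 0.105) and held with the gene-length trend removed (6.01e-05 and 0.0227), though not with an estimated correlation as well (adjusted p = 0.443 and 0.477 with an estimated correlation).

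The rise of immediate-early genes was weighed apart from the length shift. All 10 called members were still called with the mRNA-length trend removed, and all 10 without albiflorin replicate 3, which had the smallest length shift (0.132) and the highest Fos (367.9 CPM). A strong heat shock is argued against. With the trend removed, 9 tested heat-shock genes had a median log2 fold change of 0.065 (from -0.144 to 0.335). The median was 0.69 over all tested immediate-early genes and 1.17 over the called ones, which were picked by their rise. Hspa4, Chordc1 and Hsp90aa1 were called higher, so a weaker heat-shock response is not excluded. A response to albiflorin and a difference in the handling or time of harvest of the cells stay open, since the labels give no times and neither was tested; the rise may come from either.

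Splitting the 6 libraries into 3 and 3 can be done in 10 ways, too few for a share under 0.05. The real split gave 1631 genes higher and 1496 lower, and the highest count in either direction among the other 9 was 1. Each of those 9 put libraries of both groups on either side, so any difference between the groups widened the spread there. Their low counts therefore do not tell a treatment effect from a difference between libraries. For lists the real split gave 12 higher and 2 lower, and the highest count of the others in either direction was 6. Since a split and its mirror are one, each real count was set against the larger of the 2 directions of every other split. Counted so, with the real split itself included, 1 split gave as many genes as the real higher count and 1 as the real lower count. For lists, again with the real split included, 1 gave as many as the real higher count and 10 as the real lower count.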
